A study of Rattus norvegicus with 63 samples.

How the data were processed

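The series holds 63 Affymetrix rat expression arrays of 31099 probe sets, 31 labelled prefrontal cortex (PFC) and 32 labelled striatum. Per the labels' protocols the striatal dissection took the rostral caudate putamen with the nucleus accumbens, and RNA came from the rats that self-administered most robustly. The labels speak of independent pools, but also of 2 to 3 rats per naive stimulant group, 5 naive controls and 3 rats per pretreated group, about as many as arrays. The labels give each array its region, its cohort, its stimulant and, for the naive cohort, its conditioning dose. In this way the arrays fell into 20 groups of 2 to 5.

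The deposited values are linear microarray intensity per probe set, 1 column per array, made with MAS5 (version not given) per the submitters' processing notes. MAS5 subtracts a local background, weighs perfect-match against mismatch probes and scales every array to a common target, so a difference in total RNA between groups cannot be seen. The deposited intensities fitted such a scaling, since the mean signal after trimming 2% of the values at each end was 500.1 to 500.2 on every array. Detection calls were not used here. The median signal per array was 120 to 156, and 18232 values under a floor of 1 were set to 1 before log2 was taken.

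Probe sets were named through the platform annotation supplied with the reference tables. It gave 1 gene symbol to 20832 probe sets, several symbols to 436 and none to 9831, of which 57 are hybridisation or spike controls. No gene was named from a probe set with several symbols. Each of the 14218 genes was represented by the probe set with the highest mean log2 signal over all arrays, and the 40% of genes with the lowest mean in a region were left out, which left 8530 genes tested per region.

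Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with an intensity trend) on log2 signal, with 1 mean per group and all arrays of the region in the fit, so that all groups shared 1 estimate of the spread (21 residual degrees of freedom in the PFC, 22 in the striatum and 43 for fits over both regions). P-values were adjusted by Benjamini-Hochberg over the 8530 genes, and a gene passed below an adjusted p of 0.05. For each region and cohort, the unweighted mean of the stimulant groups was compared with the same cohort's saline group, then each stimulant with saline, the stimulants with each other at the same conditioning dose, and 5 with 1.25 mg/kg. Differences of these effects between cohorts and between regions were tested as contrasts of the same fits. The count of genes passing in the same direction for all 3 stimulants at 5 mg/kg was set beside 20 simulations of unchanged groups that shared the saline arrays, and correlations of fold changes beside 200.

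Gene lists were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists tested, and again with the correlation estimated per list. The 29 lists hold 953 genes, 830 of them named on the arrays, 27 entries through a synonym. They cover activity genes, transmitter systems (dopamine, striatal cAMP signalling, neuropeptides, glutamate, GABA, and serotonin with noradrenaline and acetylcholine), axon guidance, the clock, heat shock with the unfolded protein response, glucocorticoid-responsive genes, chromatin enzymes, voltage-gated channels, vesicle release, oxidative phosphorylation and ribosomal proteins. The rest are markers of glial, vascular, meningeal, choroid plexus, blood, pituitary and neuronal cells and of neighbouring tissue (thalamus, hypothalamus and septum). A list needed 5 measured members, which 26 lists had in the PFC and 27 in the striatum. Blood cell markers (2 tested in each region), pituitary hormones (0 in each) and, in the PFC, choroid plexus markers (4) had too few.

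The groups, the tests, the lists, the rule for naming genes and a set of alternative settings were fixed before the data were examined. By that rule the text names, in each mean comparison and in the naive region comparison, up to 10 genes with the largest rise and 10 with the largest fall among those that passed with every stimulant group on the same side of saline, or the 5 with the smallest p where fewer than 5 passed in a direction. It also names up to 4 members per list that passed when adjusted over the list alone, up to 3 genes each way in the other comparisons, and a fixed set of immediate early, dopamine and neuropeptide genes. Of that set, Npas4 was not analysed here and 1 gene is not reported here. Drd3, Th, Slc6a3 and Fosb were below the signal filter in both regions, Drd2 in the PFC and Bdnf in the striatum.

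Alternatives fixed at the same time were quantile normalization, log2 of the signal plus a constant (21.0 in the PFC, 22.8 in the striatum, the 20th percentile of all signals), no filter and a filter of 60%, all probe sets, eBayes without the trend, only the arrays of 1 cohort, the replicate number as a block, estimated list correlations and leaving out each array. After the data were seen, the array batch as a block, fits within each batch and fits without 1 array of cortical profile were added. Replicate numbers were checked as pairs. Across regions, naive saline arrays of the same number deviated together (5 of 5 pairs above 0.1, correlations 0.229 to 0.532), so the numbers were taken to pair them there. Other groups had 2 or 3 of 3 pairs above 0.1, except naive methamphetamine at 1.25 (0 of 2) and 5 mg/kg (1 of 3, -0.569 to 0.352), where 0 arrays matched their own number best and numbers may be crossed.

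Fits were tested on simulated data with 200 of 8530 genes changed. Of 100 with a log2 change of 0.5, 91% and 75% were recovered in the naive and pretreated mean comparison of the PFC and 89% and 72% in the striatum. For a change of 1 these were 99%, 99%, 100% and 98%, and 3.06% to 6.45% of calls there were false. Real fits, with batches and a cortical-profile array, may recover fewer. Plots were drawn with matplotlib 3.10.9.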

Results

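Gene expression was measured in the prefrontal cortex (PFC) and striatum of male Wistar rats that had self-administered amphetamine, methamphetamine or methylphenidate, and in saline controls. In a naive cohort, rats first received saline injections 2 times a day for 7 days. In a pretreated cohort the stimulant groups received the later stimulant at 5 mg/kg on the same schedule. Conditioned place preference training followed, at 1.25 or 5 mg/kg in the naive and 5 mg/kg in the pretreated cohort (for methylphenidate only 5 mg/kg), and then intravenous self-administration. An infusion held 0.1 mg/kg of amphetamine or methamphetamine, or 0.25 mg of methylphenidate in 0.1 ml, so the infused doses are not matched. Tissue was taken a day after the last session.

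Each region of the naive cohort had 5 saline arrays and 3 arrays for each stimulant and dose, except 2 for methamphetamine 1.25 mg/kg in the PFC. Each group of the pretreated cohort had 3 arrays. Replicate arrays correlated at 0.931 to 0.958 across probe sets over 72 pairs (median 0.947). The labels describe pools of RNA but also give about as many rats as arrays, so whether an array, and the spread behind each p-value, stands for a pool or a rat is open.

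BioB, a bacterial transcript spiked into each hybridisation, split the naive arrays into 23 with a log2 signal of 9.35 to 10.6 (batch A) and 16 with 5.96 to 6.68 (batch B). Batch A held saline replicates 1 to 3 (saline 1 to 3 below), amphetamine 1.25 mg/kg and both methamphetamine doses; batch B held saline replicates 4 and 5, amphetamine 5 mg/kg and methylphenidate. All pretreated arrays lay between 9.01 and 10.2. Batches also differed in the 3' to 5' log2 signal ratio of the Gapdh control, a measure of RNA integrity. In the striatum of batch A it was 0.528 to 0.574 in saline and 0.579 to 1.08 in stimulant arrays of striatal profile, and that of actin 2.71 to 2.77 and 3.07 to 3.83; in batch B the Gapdh ratio was 1.14 to 1.16 and 0.917 to 1.23. In the PFC it was 0.251 to 0.369 and 0.325 to 0.7999 in batch A, and 1.02 to 1.20 and 0.584 to 1.04 in batch B. Hbb, haemoglobin beta from residual blood, was 12.1 to 13.8 on saline arrays of batch A and 9.22 to 10.5 on those of batch B, but 12.97 to 13.9 on stimulant arrays of batch B. The array labelled striatum, naive methamphetamine 1.25 mg/kg replicate 1, had a cortical profile. Its mean of striatal minus cortical markers was -1.32, against -1.97 to -0.65 on cortical arrays and 1.80 to 3.74 on the other striatal arrays. On this array Drd2, the D2 dopamine receptor, was 7.60 (other striatal arrays 11.2 to 12.2) and Slc17a7, the vesicular glutamate transporter of cortical neurons, was 10.8 (6.15 to 9.09). It was kept as labelled.

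**Figure D1:**
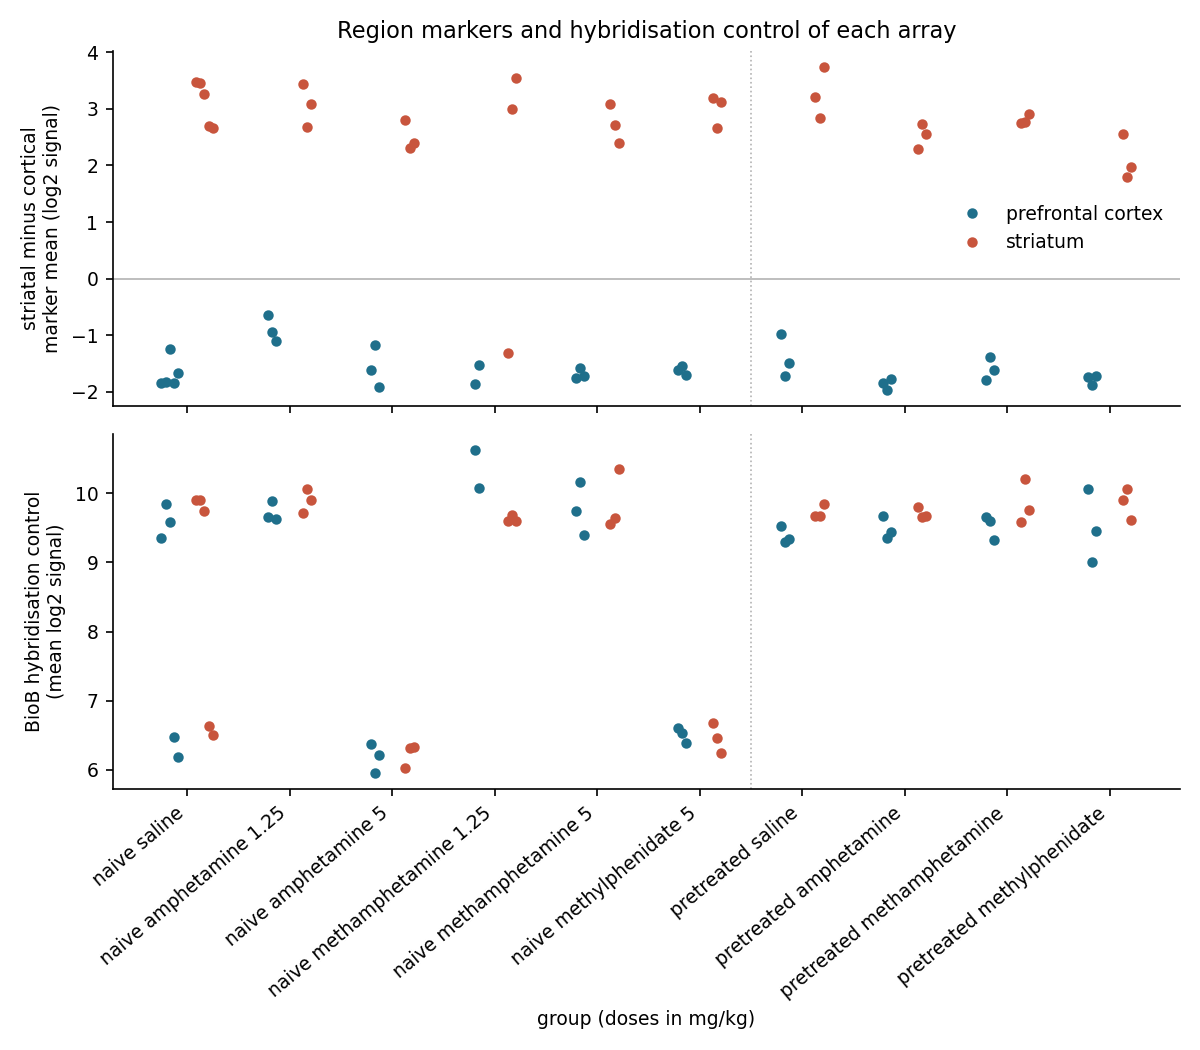
Each point is 1 array, by group and region: the mean log2 signal of striatal minus cortical markers (upper panel) and the log2 signal of the BioB hybridisation control (lower panel). One striatum-labelled array of the methamphetamine 1.25 mg/kg group lies at -1.32 among the cortical arrays.

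The saline controls first gave the contrast between regions. Dopamine and adenosine receptors of striatal projection neurons stood far higher in the naive striatum: the adenosine receptor gene Adora2a by a log2 difference of 4.77 ± 0.37 (SE), Drd2 by 4.69 ± 0.38 (7.14 ± 0.62 in the PFC and 11.83 ± 0.19 in the striatum, mean ± SD, n = 5 each) and the D1 receptor gene Drd1 by 3.74 ± 0.29 (adjusted p = 6.27e-15). Rgs9, a brake on G-protein signalling, was higher by 4.63, the nucleotide sugar transporter gene Slc35d3 by 4.50, the transcription factor gene Dach1 by 4.37, the actin-binding gene Nexn by 4.20, Syndig1l by 4.12, the neurotensin gene Nts by 3.80 and the retinoic acid receptor gene Rarb by 3.76. Genes of cortical neurons were lower there, among them Slc17a7 (-3.54 ± 0.40, adjusted p = 2.48e-10), the pyramidal neuron transcription factor genes Neurod6 (-3.58) and Bhlhe22 (-3.48), the interneuron peptide gene Vip (-3.70) and the Nogo receptor gene Rtn4r (-3.59). Tafa1 (-4.09), C1ql3 (-3.71) and Cbln2 (-3.48), which encode secreted neuronal proteins, and Exph5 (-3.64) and Car10 (-3.49) completed this group. In limma's test 3445 of 8530 genes differed in the naive cohort, 1807 higher and 1638 lower in the striatum, and 2300 in the pretreated cohort (1108 and 1192). With the array batch as a block 2522 genes differed in the naive cohort, and 3750 with the replicate number as a block (replicate block).

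The comparison of all stimulants with saline asks which genes differ after self-administration whatever the drug. In the naive PFC 5 genes passed, 1 higher and 4 lower in the stimulant groups. Acer2, an alkaline ceramidase that releases sphingosine, rose by 1.04 ± 0.19 (7.85 ± 0.43 in saline, n = 5, and 8.94 ± 0.65 in stimulant arrays, n = 14; higher in 13 of 14 arrays; adjusted p = 0.0451). Mag, the myelin-associated glycoprotein, fell by 0.53 ± 0.11 (adjusted p = 0.0483), and Nfasc, neurofascin of the node of Ranvier, by 0.57 ± 0.11 (0.0451). Adamts4, a proteoglycan-cleaving protease, decreased by 0.53 ± 0.11 (0.0483), and Pnlip, known as pancreatic lipase, by 0.58 ± 0.10 (0.0218), each lower in 14 of 14 arrays. A second Acer2 probe set gave 1.06 ± 0.26 (adjusted p = 0.192). Closest without passing were Fgl2 (0.67, adjusted p = 0.0734), the dynein light chain gene Dnal1 (0.69, 0.0775), the glucocorticoid-induced Tsc22d3 (0.39, 0.0734), the haemoglobin gene Hbb (1.78 ± 0.41, 0.102) and the cystatin gene Cst6 (0.33, 0.118) on the higher side. On the lower side these were the oligodendrocyte receptor gene Gpr37 (-0.35, 0.0734), the active zone gene Rims1 (-0.40, 0.0734), Nr2f1 (-0.36, 0.0734), Lsm11 (-0.33, 0.0800) and the G-protein regulator gene Rgs4 (-0.35, 0.106).

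Changes of these genes were larger within batch A than within batch B: Acer2 1.20 and 0.79, Mag -0.64 and -0.37, Nfasc -0.64 and -0.45, Adamts4 -0.56 and -0.49 and Pnlip -0.68 and -0.43. All 5 passed with the batch as a block, where 7 genes passed (2 higher and 5 lower), and Hbb then differed too (adjusted p = 0.000149). The count ranged from 0 without saline 4 to 9 without methamphetamine 1.25 mg/kg replicate 2, and 15 of 19 such runs moved it by more than 1.5 times. Pnlip was lost in 2 of these runs (without saline 1 or 4), Acer2 in 10, Nfasc in 14 and Mag and Adamts4 in 16, with Acer2 at 0.87 to 1.15 and Mag at -0.59 to -0.48.

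Of 26 gene lists, 8 shifted in the naive PFC (limma's camera), and 0 of these held with an estimated correlation (adjusted p after a semicolon, for lists). Oligodendrocyte and myelin markers fell: 6 of 21 when adjusted over the list alone, 1 over all genes, median -0.22, adjusted p = 5.75e-05; 0.473. Beside Mag and Gpr37, Opalin, an oligodendrocyte membrane protein gene, fell by 0.39 and Aspa, which encodes the aspartoacylase that feeds myelin lipid synthesis, by 0.48, both on the list alone (0.00527 and 0.0173). The median of this list was -0.294 within batch A (adjusted p = 3.69e-05) and -0.0356 within batch B (0.392). Cytosolic ribosomal proteins lay higher in 39 of 39 measured genes, with 0 passing singly (median 0.229, adjusted p = 9.58e-15; 0.473). Their median was 0.373 within batch A and near 0 within batch B (adjusted p = 0.851). Oxidative phosphorylation genes shifted up (0.083, adjusted p = 0.00430; 0.730; 0.132 within batch A and -0.0083 within batch B).

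Immediate early and activity genes shifted down (median -0.164, adjusted p = 0.00584; 0.473), with a median of 0.0178 within batch A (0.669) and -0.317 within batch B (6.90e-16). On this list the phosphatase gene Dusp1 fell by 0.61 when adjusted over the list alone (0.00412). Fos, a transcription factor gene induced by neuronal activity, gave -0.57 ± 0.25 (adjusted p = 0.524), Arc -0.28, Egr2 -0.35, Nr4a1 -0.27, Bdnf -0.23, Egr1 -0.08 and Homer1 -0.04. Axon guidance genes (-0.0739, adjusted p = 0.00159), glutamate receptors and postsynaptic proteins (-0.062, 0.0274) and GABA genes (-0.114, 0.0460) shifted down as well, and heat shock genes up (0.0603, 0.0227). With an estimated correlation the adjusted p was 0.473 for each of these 4. Within batch A axon guidance (0.00143) and heat shock genes (0.0196) passed, within batch B glutamate receptors (0.00740), and GABA genes in neither. Of the heat shock genes Hspb8 (0.36), Manf (0.27) and Creld2 (0.24) rose when adjusted over the list alone (0.0490 each). Per2 (0.46, 0.00291), Cry1 (0.34; 0.17 without saline 3) and Nr1d2 (0.15) of the clock, Sult1a1 (0.81, 0.0122), the glutamate transporter gene Slc1a2 (-0.32, 0.0179), the aromatic amino acid decarboxylase gene Ddc (-0.45, 0.00992) and the corticotropin-releasing hormone gene Crh (-0.37, 0.0259) passed on their lists alone, in lists that did not shift.

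Among lists that did not pass here, the adjusted p was 0.0615 for neuropeptides, 0.0887 for glucocorticoid-responsive genes, channels, synaptic vesicle release, oligodendrocyte precursors and cortical neurons, 0.282 for the circadian clock, 0.573 for dopamine synthesis and receptors and 0.142 to 0.988 for the other 10. With the batch as a block glucocorticoid-responsive genes passed (0.0369). Some of these lists passed within a batch: glucocorticoid-responsive genes with a median of 0.346 within batch A (adjusted p = 2.62e-10) and -0.280 within batch B (3.71e-08), endothelial markers with -0.216 (0.00934) and 0.303 (8.14e-06), meningeal markers within batch A alone (-0.360, 0.00934), and within batch B alone interneuron markers (-0.140, 0.00349), vesicle release (-0.0353, 0.0131) and channels (-0.0892, 0.0288). Drd1 (0.22), Penk (0.25), Pdyn (-0.07), Tac1 (0.00), Cartpt (0.20) and Ppp1r1b (0.11) had adjusted p of 0.631 to 0.995.

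In the pretreated PFC the genes that rose were led by the circadian clock. Per2, a repressor of the clock, rose by 0.93 ± 0.14 (9.20 ± 0.06 in saline, n = 3, and 10.13 ± 0.31 in stimulant arrays, n = 9; adjusted p = 0.00159). Nr1d2, which encodes the clock repressor REV-ERB beta, rose by 0.54 ± 0.07 (11.05 to 11.59; 6.63e-05), and the clock output transcription factor gene Dbp by 0.79 ± 0.15 (9.65 to 10.43; 0.0316). Bhlhe41, another clock repressor, rose by 0.48 ± 0.09 (0.0282), Smim3, a small membrane protein gene, by 0.74 ± 0.12 (0.00341) and Vwc2, which encodes the BMP antagonist brorin, by 0.77 ± 0.15 (0.0370). These 6 genes were higher in 9 of 9 stimulant arrays, and 0 genes passed as lower; the unadjusted p lay under 0.05 for 465 genes in limma's test. A second Nr1d2 probe set rose too (0.57 ± 0.10, adjusted p = 0.0121). The smallest p among lower genes belonged to Sphk2, a sphingosine kinase gene (-0.42, adjusted p = 0.0602), Adamts4 (-0.63, 0.0710), the striatal phosphodiesterase gene Pde10a (-0.47, 0.120), Sema4d (-0.57, 0.125) and Tm9sf3 (-0.40, 0.161). Per2 and Nr1d2 passed in each of 12 runs that left out 1 array. Without saline 3 the count was 2, the lowest of these runs, and Smim3, Dbp, Vwc2 and Bhlhe41 were lost; over the 12 runs they were lost in 1, 8, 10 and 4, with Dbp at 0.72 to 0.85. With the naive array batch as a block 10 genes passed.

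**Figure D2:**
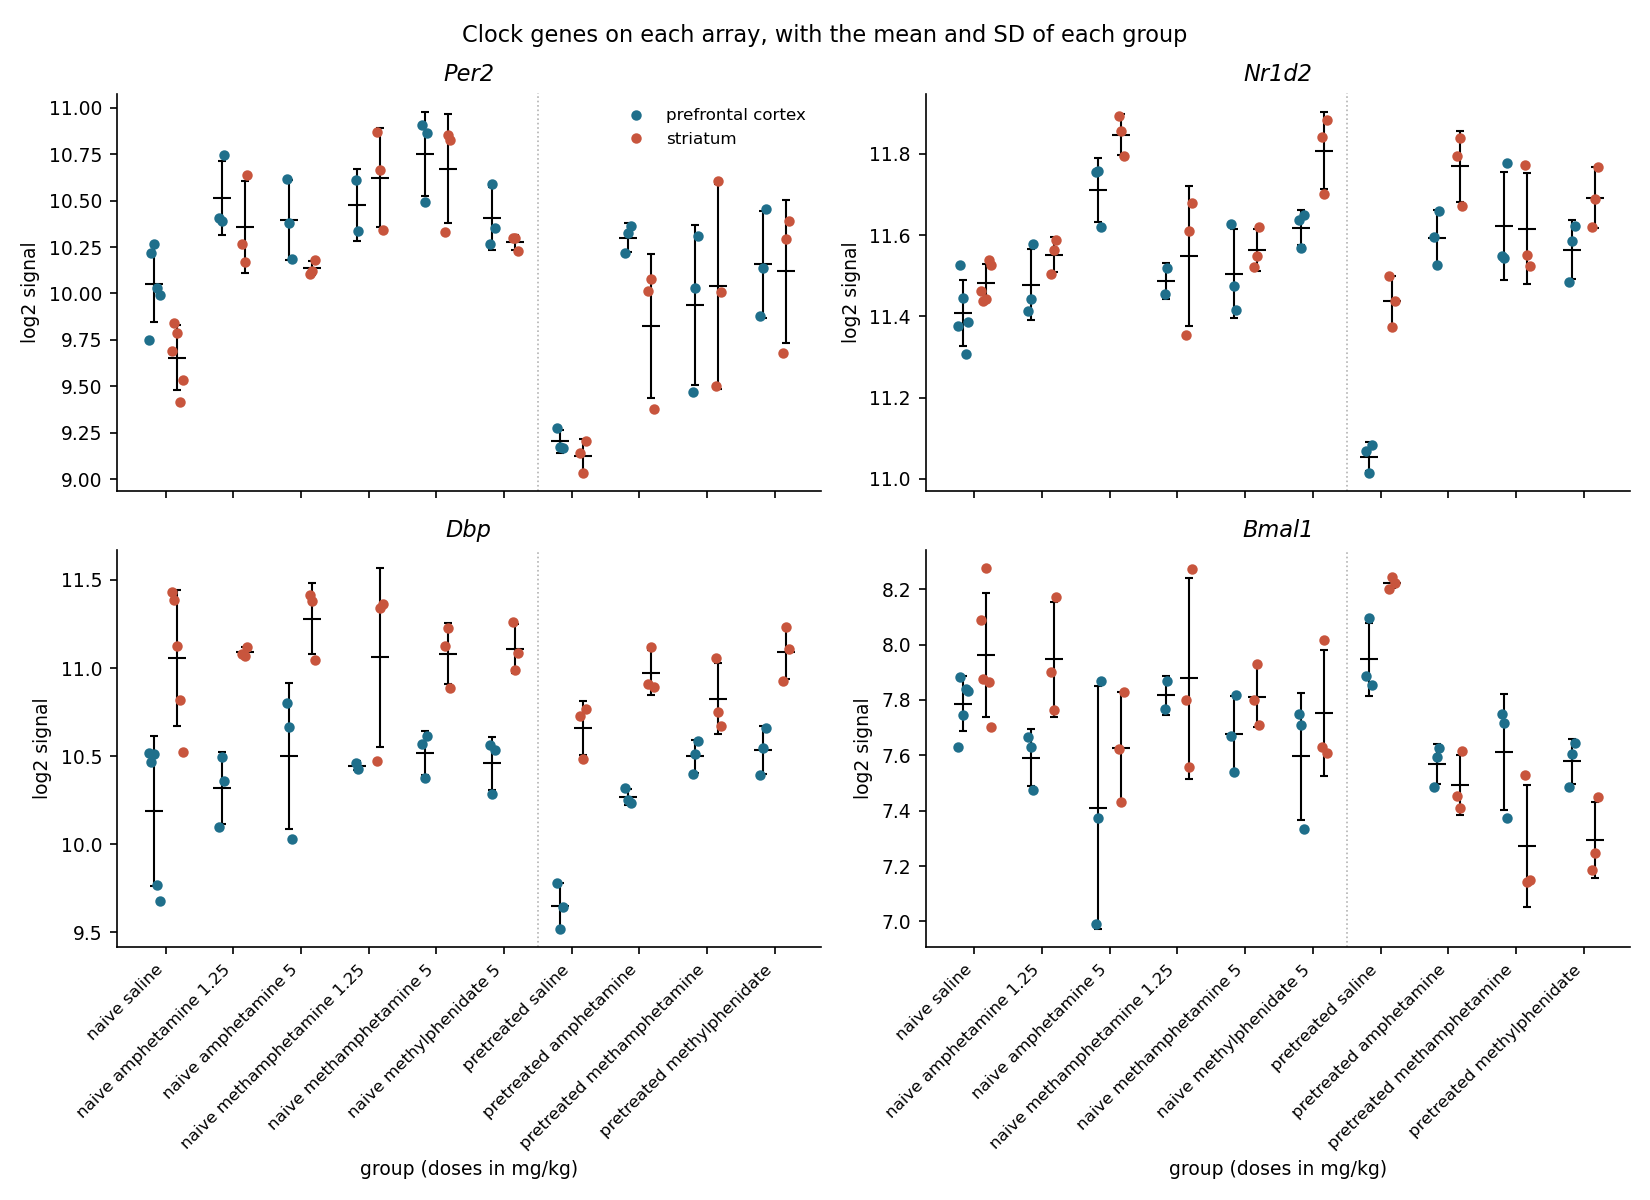
Log2 signal of the clock genes Per2, Nr1d2, Dbp and Bmal1 on each array (points), with the mean and SD of each group (bars), by group and region. In the pretreated PFC Per2 lay at 9.20 in saline and 10.13 in stimulant arrays.

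As a group, clock genes shifted up there (17 of 20 above 0, median 0.277, adjusted p = 3.71e-14), and this shift held with an estimated correlation (0.000479). Over all genes 4 rose, and 8 rose and 1 fell when adjusted over the list alone. Glucocorticoid-responsive genes shifted up too (median 0.209, adjusted p = 7.47e-11; 0.0728), 7 of 22 rising when adjusted over the list alone and 0 over all genes. These included Angptl4, an inhibitor of lipoprotein lipase (0.88, 0.00133 on the list), Per1 (0.53, 0.00133), Tsc22d3 (0.44, 0.00292) and the mTOR inhibitor gene Ddit4 (0.49, 0.00557). Markers of striatal projection neurons lay lower in 19 of 20 genes (median -0.233, adjusted p = 2.67e-11; 0.0728): Pde10a, the D1 receptor gene Drd1 (-0.63, 0.0234 on the list of dopamine genes) and Rgs9 (-0.83, 0.0194 on the list of cAMP signalling genes) fell when adjusted over the list alone, 0 over all genes. Saline replicate 1 had a striatal marker mean of 8.94, against 8.07 to 8.57 on the other pretreated cortical arrays. Without it Drd1 was -0.32, Rgs9 -0.49 and the median of this list -0.0924 (adjusted p = 0.00401), and 17 lists shifted; without saline 3, 5 did.

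The other lists that shifted in this comparison were striatal dopamine and cAMP signalling (median -0.167, adjusted p = 7.98e-05; 0.164), neuropeptides (-0.192, 0.000851; 0.262) and myelin markers (-0.151, 0.000353; 0.498), with Mag at -0.55 (0.00753 on the list). Axon guidance genes (-0.0739, 0.0105; 0.508), interneuron markers (-0.113, 0.0292; 0.498) and immediate early genes (-0.125, 0.0491; 0.633) shifted down, and astrocyte markers up (0.0725, 0.0473; 0.633). With the naive array batch as a block the adjusted p of the immediate early list was 0.0581. Fos gave -1.05 ± 0.32 (adjusted p = 0.367 over all genes, 0.0292 over the list alone). Qdpr, which regenerates the cofactor of dopamine synthesis, rose on the dopamine list alone (0.45, 0.0194) while that list did not shift (adjusted p = 0.159). Arc (-0.43), Bdnf (-0.29), Cartpt (-0.50), Egr1 (-0.15), Egr2 (-0.32), Homer1 (-0.18), Nr4a1 (-0.32), Pdyn (-0.21), Penk (-0.24), Ppp1r1b (-0.37) and Tac1 (-0.41) did not pass, with adjusted p of 0.673 or more. Without saline 1 Penk was 0.01, Pdyn 0.03, Tac1 -0.08, Cartpt -0.17, Ppp1r1b -0.23, Arc -0.24, Egr2 -0.15 and Bdnf -0.45, and the medians of the cAMP signalling and neuropeptide lists were -0.0977 and -0.109 (adjusted p = 0.00865 and 0.00401). The myelin median was -0.273 without saline 1 (1.21e-08), -0.0880 without 2 (0.0239) and -0.0909 without 3 (0.159), and that of astrocyte markers 0.121 (0.00401), 0.0367 (0.1703) and 0.0424 (0.308). Without saline 3 axon guidance genes (0.308), interneuron markers (0.317) and immediate early genes (0.481) were lost too. Median and mean lay on opposite sides of 0 for microglia, oligodendrocyte precursor and cortical neuron markers, which did not shift (0.413, 0.938 and 0.659).

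In the naive striatum Per2 rose as well, by 0.76 ± 0.14 (9.65 ± 0.18 in saline, n = 5, and 10.41 ± 0.28 in stimulant arrays, n = 15; 15 of 15 arrays; adjusted p = 0.0192). The chaperone gene Dnajb1 rose by 0.38 ± 0.07 (0.0192; 13 of 15) and the ephrin receptor gene Epha3 by 0.51 ± 0.11 (0.04997; 15 of 15). Genes that fell were Pnlip (-0.68 ± 0.11, 0.00669), the small GTPase gene Rras2 (-0.46, 0.04997), Zfp365 (-0.44, 0.0471), Elovl1, an elongase of very long chain fatty acids (-0.44, 0.0471), and Col4a5, a basement membrane collagen (-0.43, 0.0455). These 8 genes, 3 higher and 5 lower, passed with the batch as a block, where 16 did, and without the array of cortical profile, where 21 did. Next to the threshold lay the galactosyltransferase gene B4galt6 (0.30, 0.0554), Ccdc137 (0.38, 0.0554), Zbtb11 (0.34, 0.0606), the chaperone gene Chordc1 (0.34, 0.0666) and the lipolysis inhibitor gene G0s2 (0.60, 0.0670).

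Within batches A and B the change of Per2 was 0.78 and 0.73, of Pnlip -0.84 and -0.42, of Dnajb1 0.62 and 0.02, of Rras2 -0.66 and -0.18, of Elovl1 -0.58 and -0.22, of Col4a5 -0.61 and -0.16 and of Zfp365 -0.43 and -0.46. Epha3 was 0.29 within batch B and below the filter in the batch A fit. The count ranged from 1 without saline 1 to 21 without the array of cortical profile, and 18 of 20 such runs moved it by more than 1.5 times. Pnlip passed in all 20 runs and Per2 and Dnajb1 in all but those without saline 1 or 2, while Epha3 was lost in 13, Rras2 in 15, Elovl1 in 14 and Zfp365 and Col4a5 in 12; Per2 ranged from 0.70 to 0.81 and Pnlip from -0.71 to -0.63.

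Glial markers shifted down in the naive striatum, and interneuron markers up, although 0 of 11 list shifts held with an estimated correlation. Of 21 myelin markers 8 fell when adjusted over the list alone and 0 over all genes (median -0.217, adjusted p = 7.56e-07; 0.408). Examples are the myelin lipid genes Ugt8 (-0.69), Fa2h (-0.50) and Aspa (-0.50) and the myelin membrane gene Pllp (-0.45). The median was -0.356 within batch A (adjusted p = 2.19e-07) and -0.0239 within batch B (0.675). Astrocyte markers (-0.114, 0.000771), oligodendrocyte precursor markers (8 of 8 below 0, -0.152, 0.0228) and choroid plexus markers (-0.275, 0.0145) shifted down, each with an adjusted p of 0.408 with an estimated correlation. The glial filament gene Gfap fell by 0.47 on the astrocyte list alone (0.0269).

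Interneuron markers shifted up (12 of 14 above 0, median 0.222, adjusted p = 0.000925; 0.126), with Npy, neuropeptide Y, at 0.22 (0.0139 on the neuropeptide list) and Reln, reelin, at 0.33 (0.0440) past the list threshold. Within batch B their median was -0.00647 (0.670), and within batch A 0.307. Heat shock genes (0.0798, 0.00166), neuropeptides (0.220, 0.0228), channels (0.0814, 0.0324) and synaptic vesicle genes (0.0968, 0.0108), with Rab3a at 0.27 (0.0417 on the list), shifted up, each at 0.408 with an estimated correlation. Of the heat shock genes Dnajb1 rose over all genes, and it, Chordc1 and Manf (0.28) when adjusted over the list alone. Striatal projection neuron markers (-0.229, 0.0108) and cAMP signalling genes (-0.198, 0.0162) shifted down, with an adjusted p of 0.755 each with an estimated correlation; without the array of cortical profile their adjusted p was 0.444 and 0.104. Without that array the circadian clock passed (0.0399, against 0.0712 with it). Within batches A and B the medians were -0.428 and 0.000546 for projection neurons, -0.409 and 0.0175 for cAMP genes, 0.220 and -0.0058 for vesicle genes and -0.276 and -0.00910 for oligodendrocyte precursors. Of the 11 lists, 10 passed within batch A and 1, choroid plexus markers (-0.432, 0.0480), within batch B.

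Single list members past their list's threshold in lists that did not shift were the deacetylase gene Sirt2 (-0.47, 0.00273 on the list; 0.0554 over all genes, 0.00178 with the batch as a block), the DNA methyltransferase gene Dnmt3a (-0.32), Sox4 (-0.31, 0.0118), Ddc (-0.50, 0.0224), Nr1d2 (0.18, 0.0244), Gadd45b (0.58, 0.0299; 0.36 without saline 3), the cyclooxygenase gene Ptgs2 (0.52, 0.0323) and Arc, a synaptic immediate early gene (-0.56, 0.0407). Cartpt was 0.44 (adjusted p = 0.359) and Fos -0.40 (0.614). Drd1 was -0.05, Drd2 -0.26, Penk -0.12, Pdyn 0.07, Tac1 -0.09 and Ppp1r1b -0.25, and without the array of cortical profile 0.18, 0.03, 0.08, 0.27, 0.12 and -0.05. Egr1 (-0.04), Egr2 (-0.24), Nr4a1 (-0.19) and Homer1 (0.05) did not pass. Of lists that did not shift, median and mean differed in sign for glutamate receptors, serotonin and related genes, oxidative phosphorylation, endothelial markers and neighbouring tissue (adjusted p of 0.764 to 0.998). Some passed in opposite directions within batches A and B: immediate early genes (0.261, 0.000426; -0.179, 0.000178), glucocorticoid-responsive genes (0.319, 6.30e-05; -0.231, 0.00613) and endothelial markers (-0.281, 0.00816; 0.430, 0.000165). Dopamine genes (-0.162, 0.0431) and cortical neuron markers (0.283, 0.0355) passed within batch A alone, and neighbouring tissue (-0.598, 0.00181), the clock (0.0660, 0.0340) and ribosomal proteins (-0.0899, 0.0340) within batch B alone.

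**Figure D3:**
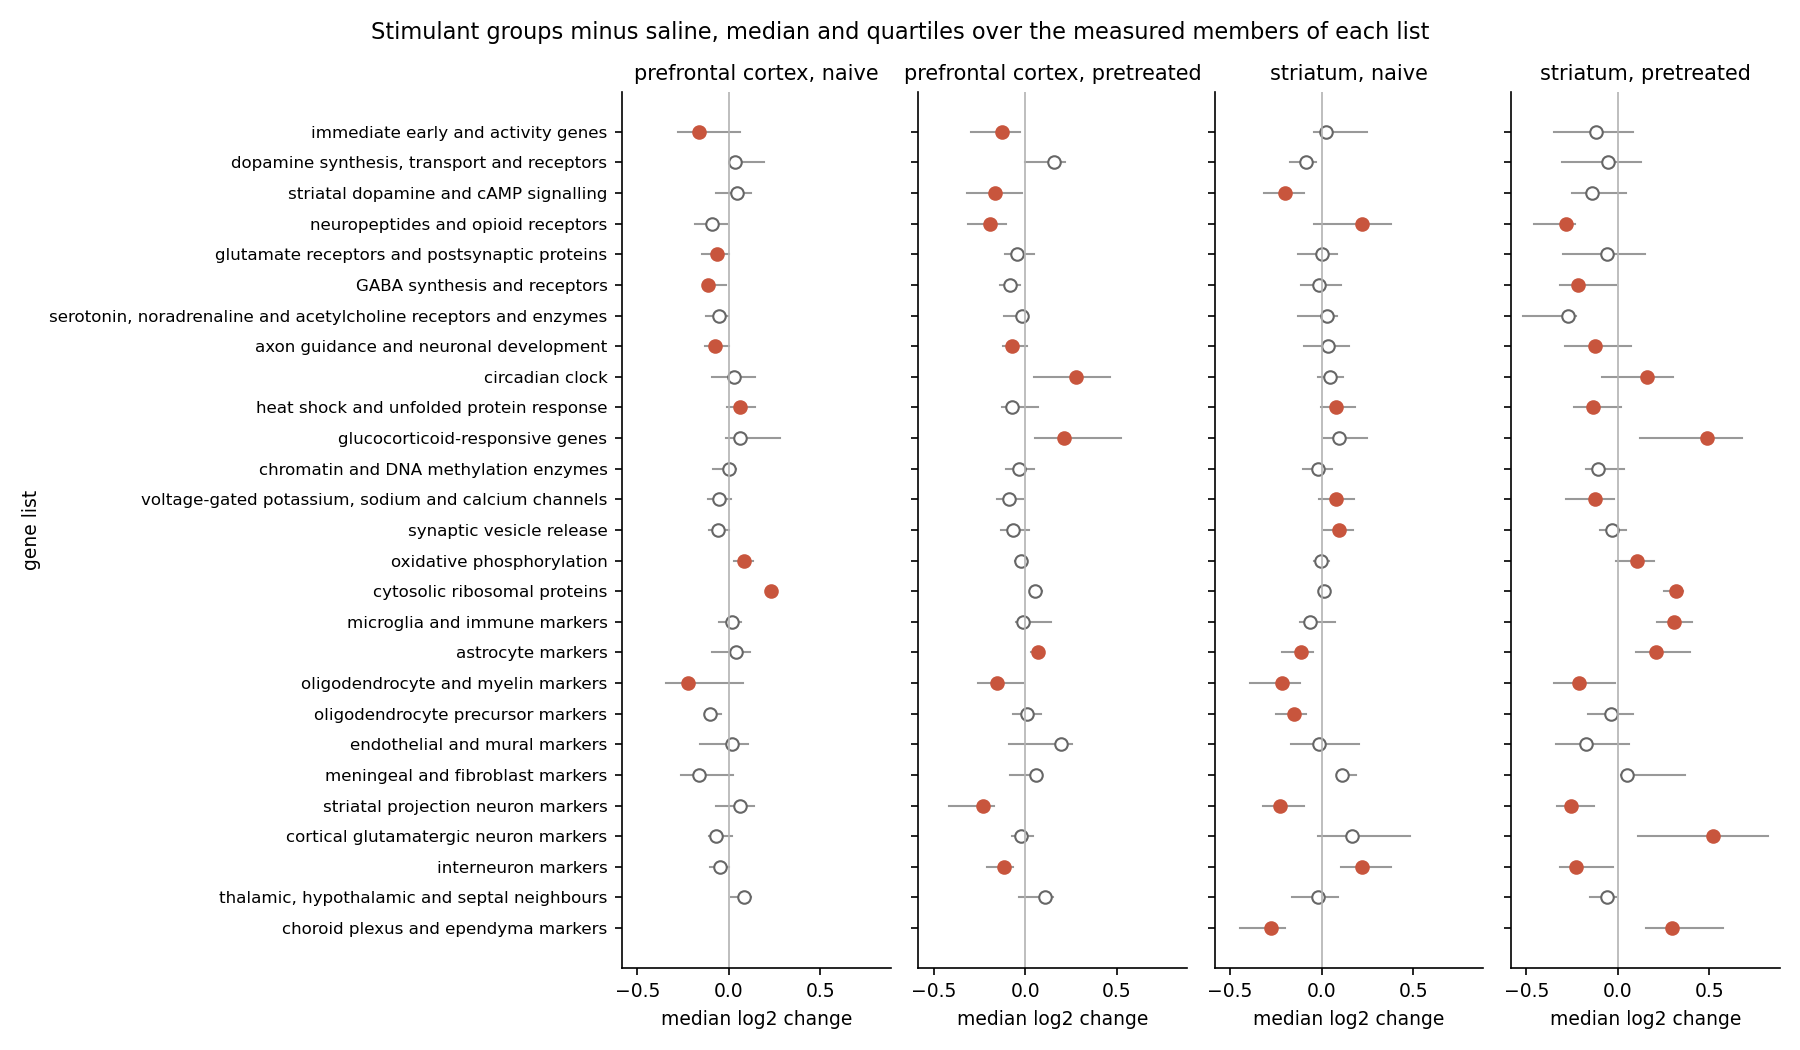
Median log2 change of each gene list in stimulant groups minus saline (points; lines join the quartiles over the list's measured members), for each region and cohort, with filled points at an adjusted p below 0.05 in camera with the preset correlation. The circadian clock in the pretreated PFC (median 0.277) is the list that also passed with an estimated correlation (0.000479).

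In the pretreated striatum 31 genes changed, 18 higher and 13 lower, each in 9 of 9 stimulant arrays for those named. The CB1 cannabinoid receptor gene Cnr1 fell by 0.74 ± 0.13 (13.07 ± 0.14 in saline, n = 3, and 12.33 ± 0.20, n = 9; adjusted p = 0.00816), and the core clock activator gene Bmal1 by 0.87 ± 0.14 (8.22 ± 0.02 and 7.35 ± 0.18; 0.00481). Per2 rose by 0.87 ± 0.18 (9.13 to 9.99; 0.0264), and the homeobox gene Msx1 by 0.84 ± 0.14 (0.00481). Syntaphilin, Snph, which docks axonal mitochondria, rose by 0.53 ± 0.10 (0.0109), the mitochondrial carrier gene Slc25a23 by 0.60 (0.0403) and the motor protein gene Kif5a by 0.54 (0.0465), while the fission GTPase gene Dnm1l fell by 0.71 (0.0253).

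Glutamine synthetase, Glul, rose by 0.45 (0.0241), Mlc1 by 0.51 (0.0435), the phagocytic receptor gene Mertk by 0.76 (0.0425) and the intermediate filament gene Synm by 0.63 (0.0264). Mtmr1 (0.83, 0.0458), Hopx (0.74, 0.0468) and Cyp4f4 (0.71, 0.0241) also rose. The transporter gene Slc16a6 (-0.99 ± 0.21, 0.0278), the sialyltransferase gene St8sia3 (-0.88, 0.0241), the TGF-beta inhibitor gene Smad7 (-0.66, 0.0488), the sterol synthesis gene Erg28 (-0.59, 0.0403), the chaperone gene Hspa4l (-0.51, 0.0465), Rgs4 (-0.48, 0.0403), the pseudokinase gene Trib2 (-0.46, 0.0337) and the Slit receptor gene Robo2 (-0.42, 0.0264) fell. Without the naive array of cortical profile, which widens the shared spread, 163 genes passed (84 higher and 79 lower), and with the naive batch as a block 74. Leaving out 1 array of this comparison gave from 0 genes without saline 1 to 163 without methamphetamine replicate 1, and 10 of 12 runs moved the count by more than 1.5 times. Bmal1 and Msx1 were lost only without saline 1 or 3, Cnr1 without any 1 of the 3 saline arrays (-0.82 to -0.69) and Per2 in 4 runs.

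Of 27 lists, 16 shifted in the pretreated striatum and 0 held with an estimated correlation. Astrocyte markers shifted up (19 of 20 above 0, median 0.207, adjusted p = 2.26e-07; 0.278): 2 rose over all genes and 7 when adjusted over the list alone, among them Aldoc (0.37) and S100b (0.38). Glucocorticoid-responsive genes shifted up (17 of 22 above 0, median 0.489, adjusted p = 1.66e-07; 0.278), with 0 passing over all genes and 12 rising when adjusted over the list alone: the metallothionein gene Mt2A by 1.13 ± 0.27 (0.00532), Klf15 by 0.68 (0.00532), Tsc22d3 by 0.65 (0.00532) and Bcl6 by 0.65 (0.00606). Clock genes shifted up (0.161, 0.0261; 0.278), with 5 rising and 1, Bmal1, falling when adjusted over the list alone; Nr1d2 was at 0.26 (0.00579). The clock list was lost without saline 2 (0.106, 0.101) or 3 (0.167, 0.0624).

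Microglial markers lay higher in 13 of 14 genes (0.306, 0.000180; 0.278), with the complement gene C1qc rising by 0.73 on the list alone (0.0459). Cortical glutamatergic neuron markers shifted up too (0.519, 0.000936; 0.278), and Emx2 (0.51, 0.00969), Lhx2 (0.53, 0.00969), Rorb (0.53, 0.0289) and Nr4a2 (1.36 ± 0.46, 0.0288; 0.89 without saline 3) rose when adjusted over the list alone; all 4 encode transcription factors. Ribosomal proteins were higher in 38 of 39 genes (0.316, 4.91e-15; 0.318), and oxidative phosphorylation (0.107, 0.0127; 0.773) and choroid plexus markers (0.294, 0.0428; 0.420) shifted up. Without saline replicates 1, 2 and 3 in turn the oxidative phosphorylation median was 0.0405 (0.328), 0.0709 (0.0750) and 0.171 (6.55e-06); choroid plexus markers were lost without 2 or 3 (0.0839 and 0.0826), and the median of cortical neuron markers was 0.333 without 3.

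Striatal projection neuron markers lay lower there in 20 of 22 genes (median -0.257, adjusted p = 0.0486; 0.787), with Rgs4 falling over all genes and on the list alone; the adjusted p was 1.32e-06 without the naive array of cortical profile and 0.0552 with the batch as a block. GABA genes (-0.219, 0.0112; 0.278) included the receptor subunit gene Gabra4 (-0.63, 0.0128 on the list) and Gphn, gephyrin of inhibitory synapses (-0.34, 0.00326). Neuropeptides (-0.284, 0.0177; 0.301), channels (-0.124, 0.0261; 0.351), interneuron markers (-0.231, 0.0379; 0.278) with Reln (-0.48) and Npy (-0.23; -0.13 without saline 2), and myelin markers (-0.210, 0.0261; 0.562) followed. Axon guidance genes shifted down (-0.125, 0.0261; 0.436), 3 rising and 7 falling when adjusted over the list alone and 1, Robo2, falling over all genes; the adhesion gene Cntn4 (-0.65), the neurotrophin receptor gene Ntrk3 (-0.57) and midkine, Mdk (0.44), were among them. Heat shock genes shifted down (-0.133, 0.0261; 0.351), with Stip1 (-0.43), Hspa5 (-0.36) and Hsp90b1 (-0.31) falling and Hspb8 (0.45) rising on the list alone. Of the lists that fell, projection neurons were lost without any 1 of the 3 saline arrays (0.0712 to 0.0832), axon guidance without 1 or 2 (0.0681 and 0.112), channels, interneurons and myelin without 2 (0.0839, 0.202 and 0.264) and heat shock genes without 3 (-0.0799, 0.101).

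In lists that did not shift as a whole, Grin2b (-0.52), Dlg3 (-0.34), Camk2a (0.37) and Homer1 (-0.35) of the glutamate synapse, Nrxn3 (-0.38), Maob, monoamine oxidase B (0.39, 0.00535), Ddc (-0.53) and Egr1 (-0.39, 0.0370) passed on their lists alone, as Kcnh3 (0.41) did among channels. Without the array of cortical profile cAMP signalling genes passed (0.0319, against 0.487 with it), and so did serotonin, noradrenaline and acetylcholine genes (0.00255 against 0.0622). Arc was -0.57, Fos -0.73, Egr2 -0.61, Nr4a1 -0.26, Drd1 -0.32, Drd2 -0.30, Penk -0.27, Pdyn -0.28, Ppp1r1b -0.13 and Cartpt -0.66, with adjusted p of 0.195 to 0.875. Tac1, the substance P precursor gene, was -0.46 (adjusted p = 0.514), and 0.0211 without that array. Dopamine genes did not shift (0.763).

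In the naive PFC methamphetamine lowered Elavl1, which encodes the RNA-binding protein HuR: by -2.05 ± 0.26 at 1.25 mg/kg (10.65 ± 0.29 in saline, n = 5, and 8.60 ± 0.01, n = 2; adjusted p = 8.37e-05) and by -1.54 ± 0.22 at 5 mg/kg (9.11 ± 0.49, n = 3; 0.00144). With the batch as a block these were -1.88 (0.00181) and -1.37 (0.0255). In the striatum methamphetamine 5 mg/kg lowered it by -1.45 ± 0.28 (10.72 ± 0.24 to 9.27 ± 0.14; 0.0174), or -1.34 with the block (0.0607); it passed in every run without 1 array in the PFC (-2.12 to -1.93 and -1.72 to -1.26), but in the striatum not without methamphetamine replicate 1 or 3 (-1.51 to -1.35 over 8 runs). The other Elavl1 probe sets gave -0.19 ± 0.14, -0.05 ± 0.12 and -0.26 ± 0.13 for 1 and -0.81, -1.26 and -0.97 for the other in these 3 comparisons, and none passed. In the pretreated cohort Elavl1 lay at 10.73 ± 0.11 after methamphetamine and 10.57 ± 0.36 in saline in the PFC, and at 10.48 and 10.59 in the striatum. Acer2 rose most with amphetamine 1.25 mg/kg, by 1.94 ± 0.27 (9.79 ± 0.36, n = 3; 0.000565; 2.17 with the block), and its second probe set passed too (1.94 ± 0.36, 0.0185).

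**Figure D4:**
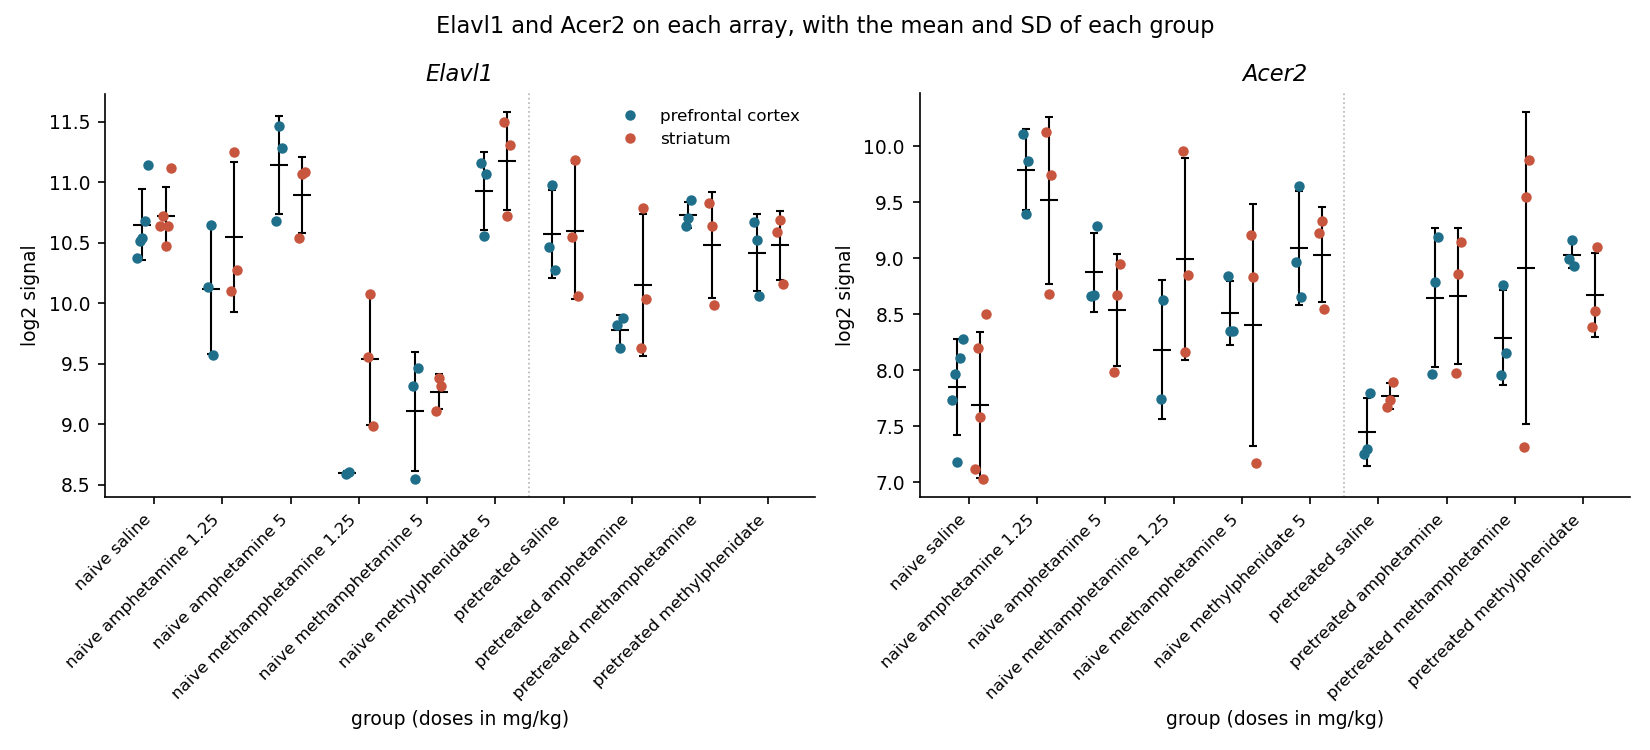
Log2 signal of Elavl1 and Acer2 on each array (points), with the mean and SD of each group (bars), by group and region. Elavl1 lay at 8.60 and 9.11 in the naive PFC after methamphetamine 1.25 and 5 mg/kg against 10.65 in saline.

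Amphetamine 1.25 mg/kg changed 42 genes in that region (21 higher and 21 lower), with the sulfotransferase gene Sult1a1 (1.80) and the calmodulin-binding gene Pcp4l1 (1.39) among those that rose and Arhgap25 (-0.94), Mex3b (-0.68) and Opalin (-0.67) among those that fell. Its 3 arrays had striatal minus cortical markers of -1.11 to -0.65, above the other naive PFC arrays (-1.91 to -1.18). With the batch as a block 20 genes passed, 8 of them shared, and Arhgap25 (0.113) and Mex3b (0.0868) were lost; the count was 2 without amphetamine replicate 1 and 71 without saline 1. Methamphetamine 1.25 mg/kg changed 950 genes (410 and 540) from 2 arrays: the GABA-synthesising enzyme gene Gad2 (-1.30) and C2cd2l (-1.20) fell, and Cmc1 (1.39), neuronatin, Nnat (1.32), and Rbis (1.15) rose. With the block 417 passed (350 shared) without Gad2 (0.106), Nnat (0.0915) and Rbis (0.0851), within batch A 53, and without methamphetamine replicate 1 only 6; that array had a Gapdh 3' to 5' ratio of 0.7999, against 0.251 to 0.585 on the other batch A arrays of the PFC. Amphetamine 5 mg/kg raised Dnal1 (1.56, 0.000472; 0.0697 with the block), its 1 gene. Methamphetamine 5 mg/kg changed 3, with Pnlip (-0.71) and the kinase gene Clk1 (0.71) beside Elavl1, both lost with the block (0.0934 and 0.104). Methylphenidate gave 0 in limma's test, with 1149 genes at an unadjusted p under 0.05, 2 with the block and 54 without saline 4.

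In the pretreated PFC amphetamine raised Per2 (1.10 ± 0.17) and Nr1d2 (0.54; 0.00291 each), its 2 genes, and methamphetamine raised Nr1d2 (0.57 ± 0.08, 0.00115), its 1 gene. Methylphenidate changed 8 (7 and 1): Acer2 rose by 1.58 ± 0.30 (0.0176; lost in 5 of 6 runs without 1 array), Per2 by 0.95 (0.0111) and the cystathionine synthase gene Cbs by 0.85 (0.00996). The count for methylphenidate was 2 without saline 3.

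In the naive striatum amphetamine 1.25 mg/kg lowered the desaturase gene Scd by -1.37 ± 0.20 and the sterol demethylase gene Cyp51 by -0.91 ± 0.14 (0.00154 each), together with Gfap (-0.92, 0.0218). Dnajb1 (0.58), the kinase gene Pim2 (0.62) and Ripor2 (0.45) rose. In all 29 genes passed (4 and 25), 30 with the block (15 shared, without Pim2 and Ripor2), 14 within batch A and 4 without amphetamine replicate 1. Methamphetamine 5 mg/kg changed 28 (14 each way): Per2 rose by 1.02 (0.0138; 0.0607 with the block), the transcription factor gene Klf5 by 0.91 (0.0457; 0.0192) and Rbm12b by 0.76 (0.0196; 0.0759), and Entpd5 (-0.93; 0.0771 with the block) and the myelin lipid gene Fa2h (-0.85; 0.0288; -0.49 without methamphetamine replicate 3) fell. The count was 24 with the block, 46 without the array of cortical profile and 5 without methamphetamine replicate 3. Methamphetamine 1.25 mg/kg, the group that holds the array of cortical profile, changed 16 (6 and 10), with Per2 (0.97), Cadm3 (0.84) and Twf2 (0.73) up and Pnlip (-0.88), Opalin (-0.88) and Msx1 (-0.76) down. Without that array 0 passed, and these 6 had adjusted p of 0.0995 to 0.347.

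Methylphenidate lowered Arc by -1.44 ± 0.27 (9.36 ± 0.37, n = 5, to 7.92 ± 0.23, n = 3; 0.0209), the metalloprotease gene Mmp14 (-1.10) and Dnm3 (-1.06) and raised Phip (0.59) and Tpd52l2 (0.49), 11 genes in all (2 and 9). Arc was lost in 4 of 8 runs without 1 array (-1.56 to -1.31). With the block 1 passed and these 5 had adjusted p of 0.345 to 0.999; the count was 118 without saline 5 and 0 without saline 3. Amphetamine 5 mg/kg gave 0 genes (limma; 1250 at an unadjusted p under 0.05), 40 without the array of cortical profile, 1 with the block and 145 without saline 5. In the pretreated cohort methamphetamine changed 60 (37 and 23): Mt2A (1.94 ± 0.33, 0.0243; lost in 5 of 6 runs without 1 array, 1.48 to 2.55), the albumin gene Alb (1.88; 1.14 without saline 2) and Gpatch4 (1.47) rose, and the endothelial transporter gene Slco1c1 (-1.18), Prom1 (-1.32) and Cyp2j10 (-1.34) fell. The count was 0 without saline 1 and 284 without methamphetamine replicate 1. Methylphenidate changed 7 (4 and 3), with Msx1 (0.84), the calcium sensor gene Ncs1 (0.63; 0.0559 with the block) and Snph (0.62) up and Bmal1 (-0.93 ± 0.17, 0.0480), Cnr1 (-0.80) and Rgs4 (-0.63) down; 45 passed without the array of cortical profile and 0 without saline 1. Amphetamine gave 0 (744 at an unadjusted p under 0.05).

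Nr1d2 passed in the same direction for all 3 stimulants at 5 mg/kg in the pretreated PFC, but not with that cohort's arrays alone. Simulated unchanged groups had at most 0. Limma gave 0 in the other 3 settings. At an unadjusted p under 0.05, 16 genes rose and 19 fell with all 3 stimulants in the naive PFC (at most 12 and 12 in 20 such simulations), 34 and 25 in the pretreated (20 and 15), 45 and 27 in the naive striatum (16 and 18) and 141 and 114 in the pretreated striatum (21 and 18); the simulated genes vary independently, unlike real ones. Across genes, which are not independent replicates, fold changes of amphetamine and methylphenidate correlated at 0.586 in the naive PFC and 0.7005 in the naive striatum, against 0.375 and 0.373 from the shared saline arrays alone. With the saline arrays split, the medians were 0.291 and 0.447, and the covariance lay 0.0128 and 0.0225 above the simulated one. Those 2 groups share batch B. For methamphetamine these correlations were 0.0159 and 0.262 with amphetamine and 0.0706 and 0.206 with methylphenidate, with covariance differences of -0.00688 to 0.00197. In the pretreated cohort, where 3 saline arrays cannot be split, correlations were 0.446 to 0.565 in the PFC and 0.630 to 0.753 in the striatum against about 0.5 from shared controls, and covariance differences were 4.22e-05 to 0.00572 and 0.0207 to 0.0273; part of the excess may come from those controls.

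At 5 mg/kg in the naive PFC 123 genes differed between amphetamine and methamphetamine (59 higher and 64 lower with amphetamine), 158 between methamphetamine and methylphenidate (61 and 97) and 0 between amphetamine and methylphenidate (limma; 441 at an unadjusted p under 0.05). Elavl1 was higher with amphetamine than methamphetamine by 2.03 ± 0.25 (6.17e-05), and methamphetamine minus methylphenidate gave -1.82 ± 0.25 (0.000535). The immediate early genes Egr2 (-1.82) and Arc (-1.44) and the link protein gene Hapln2 (-1.24) were lower with amphetamine than with methamphetamine, and Cyyr1 (1.27) and Angptl4 (1.14) higher. Angptl4 (-1.11) and Nmral1 (-0.99) were lower, and Tsc2 (0.91), Mxd4 (0.89) and Rapgef4 (0.88) higher, with methamphetamine than with methylphenidate. Methamphetamine lay in batch A and the other compounds in batch B: with the batch as a block these counts were 5 and 1, Elavl1 differed by 1.60 (0.116) and -1.38 (0.445), Hapln2 by -0.01, and Mxd4 turned to -0.06 (0.994). At 1.25 mg/kg, where both groups lie in batch A, 534 genes differed (315 and 219; 671 with the block). Gad2 (1.73), the von Willebrand factor gene Vwf (1.72) and Acer2 (1.61) were higher with amphetamine, and Tnnc2 (-1.34), Grxcr1 (-1.15) and S100a3 (-1.13) lower, against 2 methamphetamine arrays, whose striatal minus cortical markers (-1.86 and -1.52) lay below those of amphetamine; without amphetamine replicate 1 Tnnc2 was -0.63 and Grxcr1 -0.73; Acer2 was lost without amphetamine replicate 1 or methamphetamine replicate 1 (1.17 to 2.05 over 5 runs).

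At 5 mg/kg 134 genes of the naive striatum differed between amphetamine and methamphetamine (66 and 68), 133 between methamphetamine and methylphenidate (74 and 59) and 0 between amphetamine and methylphenidate (limma; 291 at an unadjusted p under 0.05). The immediate early genes Egr2 (2.24), Nr4a3 (1.90) and Fos (1.61) were higher with methamphetamine than with methylphenidate, and Elavl1 (-1.91), Cyyr1 (-1.31) and the transporter gene Slco1a4 (-1.22) lower. Foxj1 (-1.78), Nr4a3 (-1.77) and Egr2 (-1.64) were lower with amphetamine than with methamphetamine, and Elavl1 (1.63), Nkx6-2 (1.23) and Slco1a4 (1.10) higher. With the batch as a block both counts were 1, and none of these genes passed. At 1.25 mg/kg 0 genes differed (limma; 473). Over all 3 compounds, 78 genes differed in the PFC and 124 in the striatum, 2 and 1 with the block. Batch B has no methamphetamine to test. In the pretreated cohort 0 genes differed in each pair (limma; 365, 519 and 647 at an unadjusted p under 0.05 in the PFC, 263, 330 and 711 in the striatum).

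Between conditioning doses, 243 genes differed in the PFC for the mean of amphetamine and methamphetamine (131 higher and 112 lower at 5 mg/kg). Pcp4l1 (-0.98 ± 0.17, 0.00777), Nnat (-1.08) and the cadherin gene Cdhr1 (-0.96) were lower, and Dnal1 (0.95 ± 0.18, 0.00993), Dock3 (0.87) and Elavl1 (0.77) higher at 5 mg/kg. The 1.25 mg/kg side holds the amphetamine arrays of high striatal markers, and amphetamine doses lie in different batches: with the batch as a block 5 genes passed and these 6 had adjusted p of 0.187 to 0.395, and within batch A, from methamphetamine alone, 0 passed. The count was 11 without methamphetamine 5 mg/kg replicate 3 and 1430 without its replicate 2. In the striatum 0 genes passed (limma; 1094 at an unadjusted p under 0.05).

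The effect of stimulants at 5 mg/kg was then compared between cohorts, which also differ in array set. Per1, a clock repressor that glucocorticoids induce, differed in the PFC by 0.90 ± 0.16 (adjusted p = 0.0279), with -0.36 ± 0.10 in the naive and 0.53 ± 0.12 in the pretreated cohort. In the striatum Msx1 differed by 1.07 ± 0.18 (0.0153), Synm by 0.92 ± 0.17 (0.0255), Snph by 0.66 ± 0.12 (0.0270) and Robo2 by -0.61 ± 0.11 (0.0255). Abhd4, a lipase of endocannabinoid synthesis that was named after its values were seen, differed by 0.61 ± 0.12 (0.0495). With the batch as a block 2 and 9 genes passed, these named by the rule among them but not Abhd4; against naive batch A arrays alone 2 and 0 did, against batch B alone 2 and 26. Per1 was lost in 14 of 26 runs without 1 array (0.81 to 1.07), Msx1 in 3 (1.01 to 1.14), Synm and Robo2 in 6 and Snph in 10. The striatal count was 0 without naive saline 2 and 135 without pretreated methylphenidate replicate 3. Between regions, 0 genes had a different mean stimulant effect in the naive or the pretreated cohort (limma; 541 and 439 at an unadjusted p under 0.05).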

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

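All tests of explanations and of other splits in this part were chosen after the results had been seen.

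Stimulant effects on Per1, a clock gene that glucocorticoids induce, and on the homeobox gene Msx1 differed between the cohorts. The difference in the effect at 5 mg/kg, pretreated minus naive, was 0.90 for Per1 in the PFC, and in the striatum 1.07 for Msx1, 0.92 for Synm, 0.66 for Snph, 0.61 for Abhd4 and -0.61 for Robo2. Each passed a test of the difference itself, Abhd4 not with the batch as a block. In the striatum 1 of 100 splits gave as many as the real 5 genes (highest other 1), and 2 of 100 within batches (7). Both shares lie under 0.05, but 0 genes passed against naive batch A arrays alone or without naive saline 2. For Per1 and the PFC 6 of 100 splits gave as many as the real 1 gene, the highest other 269, so chance cannot be excluded.

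Probe sets without a single gene name carried signals that no comparison of genes used. Among 18625 probe sets tested, 2 of these passed in the pretreated PFC, higher by 1.78 ± 0.20 (adjusted p = 1.73e-05) and 1.92 ± 0.36. The striatum had 3 in the naive cohort, at 0.48, -1.01 and -0.92, and 13 in the pretreated cohort.

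Fos, an activity-induced transcription factor gene, was 8.89 on naive striatal saline 1 against 10.05 to 10.45 on the other 4, a gap of 0.744 of the group's range. Egr1, another such gene, was 13.1 on naive striatal saline 3 against 12.8 to 12.9 (0.731), and the small heat shock gene Hspb8 was 8.65 on naive prefrontal saline 3 against 9.02 to 9.17 (0.722). These 3 of 85 values tested exceed the critical ratio of 0.71 for 5 arrays, and chance gives about 1 in 20.

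The array batch is a candidate explanation for the differences among compounds and doses in the naive cohort. Of 78 genes that differed among compounds at 5 mg/kg in the PFC, 98.7% differed between saline arrays of batches B and A in the same direction, as did 87.1% of 124 in the striatum and 88.9% of 243 between doses (correlations across genes 0.802, 0.609 and 0.783). Of 100 splits each, 2 gave as many genes for compounds in the PFC (highest other 130, real 4 without methamphetamine 1). In the striatum 1 did (89, real 30 without amphetamine 3), and for doses 6 (2249). These ignore the batch, so chance cannot be excluded. The batch follows the compounds and doses here, and whether methamphetamine itself contributes remains open: Elavl1 passed against saline with the batch as a block in the naive PFC, but did not fall in the pretreated PFC.

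A larger share of cortical tissue in the stimulant samples was tested for the pretreated striatum, where cortical markers such as Rorb and Emx2 lay higher. The median of 40 genes at least 2 log2 units higher in cortex was 0.316, which a share of 5.54% would give. That share would move the 31 changed genes, Cnr1 and Bmal1 among them, by a median of 0.00486 against the 0.536 observed, and 53 striatal genes by -0.0702, against a score of -0.259 (95% interval -0.407 to -0.111). This argues against such tissue as the whole explanation of either, although a small share remains possible. Other regions of dissection and an effect of the stimulants themselves stay open, as untested.

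In the mean comparison of the naive PFC, which named Acer2 and Mag, 5 of 100 splits gave as many as the real 5 genes, so chance cannot be excluded. The highest other, 1247, set saline replicates 4 and 5 with amphetamine 5 mg/kg replicate 2 and methylphenidate replicates 2 and 3, all of batch B, against the rest; with the batch as a block 7 genes passed, and 3 of 100 splits within batches gave as many (highest other 597). In the striatum, with Per2 and Pnlip, 3 of 100 did (real 8, highest other 529, a split that joined saline 5 with batch B arrays), and 1 of 100 within batches (2), so chance can be excluded; with the block 16 passed, and without saline 1 only 1. RNA integrity stays open there, as untested: within batch A, where most of these changes were larger, saline arrays had lower 3' to 5' ratios than every stimulant array of striatal profile. For lists, 45 of 100 splits in the PFC (real 8, highest other 15) and 19 of 100 in the striatum (real 11, highest other 18) shifted as many, so chance cannot be excluded.

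Single stimulants of the naive cohort had 56 splits each against saline; methamphetamine 1.25 mg/kg in the PFC, with 2 arrays, was not split. For amphetamine 1.25 mg/kg in the striatum, where Scd and Cyp51 fell, 2 gave as many (real 29, highest other 55), but these ignore the batch, and the highest set saline replicates 4 and 5 and amphetamine replicate 1 against the rest. Within batch A there are 10 splits, too few for a share under 0.05 (highest other 0). Methylphenidate in the PFC and amphetamine 5 mg/kg in the striatum had a real count of 0, so all 56 gave as many by design (highest other 1235 and 912). For the others chance cannot be excluded: on prefrontal arrays amphetamine 1.25 mg/kg with 4 (real 42, highest other 135), amphetamine 5 mg/kg with 4 (real 1, 1127) and methamphetamine 5 mg/kg with 6 (real 3, 387), and in the striatum methamphetamine 1.25 mg/kg with 3 (real 16, 525), methamphetamine 5 mg/kg with 3 (real 28, 788) and methylphenidate with 3 (real 11, 890). Striatal tissue in the PFC samples of amphetamine 1.25 mg/kg, whose striatal markers were high, stays open as a cause of their changes and those between doses. The prefrontal splits with 1127 and 1235 genes set the batch B arrays against batch A; blocked by batch, limma gave 1 and 2 genes.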

How the results depend on the processing

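Alternatives fixed beforehand and those added after the data were seen (the array batch as a block, fits within a batch, and fits without the array of cortical profile) were applied to 40 counts of genes or lists, all from limma. Of 407 alternative counts beside those without 1 array, 141 differed from the reported one by more than 1.5 times.

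Named genes were followed through 298 pairs of gene and comparison. The batch block moved 51 below and 5 past the threshold, leaving 126 as they were, and turned the difference of Mxd4 between methamphetamine and methylphenidate in the prefrontal cortex from 0.89 to -0.0587. Runs without 1 array moved 636 below the threshold and 69 past it, reversed 0 and shifted 25 that passed in neither fit by more than their SE. Within batch A 40 fell below, 10 moved past and 25 shifted in this way, and within batch B 19, 1 and 45.

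With all probe sets, the regions differed at 6841 in the naive and 4684 in the pretreated cohort. Mean comparisons gave 2 in the naive cortex, 12 in the pretreated cortex and 54 in the pretreated striatum. In the naive cortex amphetamine 1.25 mg/kg gave 68, methamphetamine 5 mg/kg 1 and methylphenidate 1. In the naive striatum amphetamine 5 mg/kg gave 12, methamphetamine 42 at 1.25 and 58 at 5 mg/kg and methylphenidate 101. In the pretreated cohort methamphetamine in the cortex gave 2 and methylphenidate in the striatum 0. Compounds differed at 149 in the naive cortex and 197 in the naive striatum, and cohorts at 2 in the cortex and 20 in the striatum. All 3 stimulants shared 2 in the pretreated cortex.

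Within batch A the regions differed at 2275 genes, and the mean comparisons gave 11 in the cortex and 50 in the striatum. Amphetamine 1.25 mg/kg gave 16 in the cortex and 14 in the striatum, methamphetamine 1.25 mg/kg 53 and 0, and methamphetamine 5 mg/kg 1 in the striatum. Doses differed at 0 in the cortex, and cohorts at 2 in the cortex and 0 in the striatum. Within batch B, lacking methamphetamine, the regions differed at 2161, and mean comparisons gave 2 in each. Amphetamine 5 mg/kg gave 3 in the cortex and 1 in the striatum, methylphenidate 3 in each and their difference 0. Cohorts differed at 2 in the cortex and 26 in the striatum, and 7 lists shifted in the naive striatum.

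With the array batch as a block, the mean comparison of the naive striatum gave 16. In the naive cortex amphetamine 1.25 mg/kg gave 20, methamphetamine 1.25 mg/kg 417 and methylphenidate 2, and in the striatum amphetamine 5 mg/kg and methylphenidate 1 each. Compounds differed at 2 in the cortex and 1 in the striatum, doses at 5 in the cortex, and cohorts at 2 and 9. Without the array of cortical profile, mean comparisons gave 21 in the naive and 163 in the pretreated striatum. Amphetamine 5 mg/kg gave 40, methamphetamine 1.25 mg/kg 0 and 5 mg/kg 46, and in the pretreated striatum amphetamine gave 1, methamphetamine 110 and methylphenidate 45. Compounds differed at 219 in the naive and 1 in the pretreated striatum and cohorts at 51, and all 3 stimulants shared 1 in the naive striatum. With both changes the naive striatum gave 33 in the mean comparison, 45 for amphetamine 1.25 and 1 for 5 mg/kg, 0 for methamphetamine 1.25 and 78 for 5 mg/kg and 1 for methylphenidate. Compounds then differed at 1, cohorts at 30 and regions in their naive stimulant effect at 2.

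With only the arrays of 1 cohort, mean comparisons gave 2 and 11 in the naive and pretreated cortex and 5 and 102 in the striatum. In the naive cortex amphetamine 1.25 mg/kg gave 12 and methamphetamine 5 mg/kg 1. In the naive striatum amphetamine 5 mg/kg gave 1, methamphetamine 5 at 1.25 and 6 at 5 mg/kg and methylphenidate 5. Pretreated amphetamine arrays gave 1 in each region, methamphetamine 5 in the cortex and 13 in the striatum, and methylphenidate 18 in the striatum. Compounds differed at 9 in the naive cortex, 1 in the pretreated cortex and 33 in the naive striatum, doses at 94 in the cortex, and all 3 stimulants shared 0 in the pretreated cortex.

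Replicate numbers within a region were not taken as pairs: the median correlation of arrays with the same number in different groups was -0.0191 and 0.194 in the naive and pretreated cortex and -0.0242 and 0.0270 in the striatum. Across regions they were for naive saline, where the replicate block gave 3750 genes. Numbers 4 and 5 exist only among naive saline arrays, so within a region the replicate block leaves batch A saline arrays alone to compare with. It gave 27 in the naive cortex and 238 and 58 in the naive and pretreated striatum for the mean comparisons. In the naive cortex amphetamine gave 24 at 1.25 and 654 at 5 mg/kg, methamphetamine 300 and 1 and methylphenidate 810. In the naive striatum amphetamine 5 mg/kg gave 680, methamphetamine 1.25 mg/kg 0 and methylphenidate 611. For the pretreated cohort methamphetamine gave 2 and methylphenidate 18 in the cortex, and methylphenidate 0 in the striatum. Compounds differed at 383 and 221 in the naive cortex and striatum, doses at 446 and 6, and cohorts at 9 and 380. All 3 stimulants shared 1 in the naive cortex and 4 in the naive striatum.

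With no signal filter the mean comparison of the naive striatum gave 3, amphetamine 5 mg/kg and methylphenidate in the naive cortex 2 each, and methylphenidate in the pretreated striatum 0. Compounds differed at 45 in the naive and 1 in the pretreated striatum, doses at 123 in the cortex and cohorts at 10 in the striatum. With 60% of genes left out, mean comparisons gave 0 in the naive cortex and 49 in the pretreated striatum, amphetamine 1.25 mg/kg in the cortex 27, methylphenidate in the naive striatum 0, methamphetamine in the pretreated striatum 36 and the cohort difference in the striatum 18. Without the intensity trend the pretreated striatum gave 20 for the mean and 1 for methylphenidate, methamphetamine 5 mg/kg in the cortex 1 and 1.25 mg/kg in the striatum 10. Quantile normalization gave 1 for methamphetamine 5 mg/kg in the cortex, 7 for methylphenidate in the naive striatum and 153 for doses in the cortex. With estimated correlations 0 lists shifted in the naive cortex, 1 in the pretreated cortex and 0 in the striatum of each cohort.

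Of 483 runs without 1 array, 176 moved a count by more than 1.5 times. Single stimulants in the naive cortex ranged from 2 (without amphetamine replicate 1) to 71 (saline 1) for amphetamine 1.25 mg/kg, 1 to 6 (saline 5) for 5 mg/kg, 6 (methamphetamine 1) to 1263 (methamphetamine 2) for methamphetamine 1.25 mg/kg, 1 (saline 1) to 7 (saline 3) for 5 mg/kg and 0 to 54 (saline 4) for methylphenidate. Where 1 array was left, it was assumed to vary like the other groups. In the pretreated cortex the ranges were 2 to 4 (amphetamine 3) for amphetamine, 1 to 2 (methamphetamine 1) for methamphetamine and 2 (saline 3) to 12 (methylphenidate 3) for methylphenidate. In the naive striatum they were 4 (amphetamine 1) to 47 (amphetamine 2) for amphetamine 1.25 mg/kg, 0 to 145 (saline 5) for 5 mg/kg, 0 (saline 1) to 322 (methamphetamine 3) for methamphetamine 1.25 mg/kg, 5 (methamphetamine 3) to 42 (methamphetamine 1) for 5 mg/kg and 0 (saline 3) to 118 (saline 5) for methylphenidate. In the pretreated striatum they were 0 (saline 1) to 284 (methamphetamine 1) for methamphetamine and 0 (saline 1) to 15 (methylphenidate 3) for methylphenidate.

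Compounds compared at 5 mg/kg ranged from 4 (methamphetamine 1) to 84 (methamphetamine 2) in the naive cortex, 0 to 2 (methylphenidate 3) in the pretreated cortex, 30 (amphetamine 3) to 116 (methylphenidate 3) in the naive striatum and 0 to 40 (methamphetamine 1) in the pretreated striatum. Doses ranged from 11 (methamphetamine 5 mg/kg 3) to 1430 (methamphetamine 5 mg/kg 2) in the cortex and 0 to 3 (amphetamine 1.25 mg/kg 1) in the striatum. The cohort difference ranged from 0 (naive saline 1) to 2 (naive saline 5) in the cortex and 0 (naive saline 2) to 135 (pretreated methylphenidate 3) in the striatum. Genes shared by all 3 stimulants ranged from 1 to 2 (methamphetamine 1) in the pretreated cortex and 0 to 1 (saline 4) in the naive striatum. Lists shifted ranged from 5 (saline 3) to 10 (saline 1) in the naive cortex, 5 (saline 3) to 17 (saline 1) in the pretreated cortex, 7 (saline 4) to 12 (saline 2) in the naive striatum and 8 (saline 2) to 17 (methamphetamine 1) in the pretreated striatum.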

Other observations

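All tests in this part were chosen after the results had been seen.

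A shift of clock phase may underlie the clock gene changes of the pretreated cohort. Targets of the activators (Per2, Nr1d2, Dbp and others) minus the activators (Bmal1, Clock and Npas2) rose by 0.659 in the PFC and 0.568 in the striatum, genes seen to change among them. A rise of targets alone stays open: repressors among them (Nr1d2) may lower activators. Activators that did not pass gave -0.2004 in the PFC (3 genes; exact two-sided permutation p = 0.00455, the smallest of 220 splits) and -0.0481 in the striatum (Clock and Npas2; p = 0.591), where a fall of Bmal1 without the other activators stays open and the clock list lost its call without saline 2 or 3. Glucocorticoid response as sole cause stays open. With each array's score of 20 such genes as covariate, targets minus activators gave 0.552 (95% interval 0.350 to 0.754) and 0.454 (0.217 to 0.692). Such genes rose too, and a noisy score adjusts too little. The hour of collection cannot be told from a stimulant effect, as 0 labels give it. Nr1d1 (-0.09), Usp2 (-0.15) and Npas2 (0.14) in the striatum moved against the shift, none passing.

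In the mean comparison of the pretreated PFC, where Per2 and Nr1d2 led, 1 of 100 splits gave as many as the real 6 genes (highest other 2; 2 genes without saline 3), and in the striatum, where Bmal1 and Cnr1 fell, 2 of 100 gave as many as 31 (highest other 44; 0 without saline 1), so chance can be excluded in both. For lists chance stays open. In the striatum 16 shifted (1 of 100, highest other 12, median 6), but 8 without saline 2 and 0 with an estimated correlation. In the PFC 10 did (32 of 100, highest other 17). For Nr1d2, shared by all 3 stimulants, 2 of 100 PFC splits shared 1 (highest other 1). Chance can be excluded, but pretreated arrays alone gave 0. Single stimulants had 10 splits each, too few for a share under 0.05. On prefrontal arrays the real value and highest other were 2 and 0 for amphetamine (1 as large), 1 and 0 for methamphetamine (1) and 8 and 2 for methylphenidate (1), and in the striatum 0 and 0 for amphetamine (10), 60 and 0 for methamphetamine (1) and 7 and 0 for methylphenidate (1).

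For the regions, with Drd2 and Slc17a7 at their ends, 1 of 100 splits of the naive saline arrays gave as many as the real 3445 genes (highest other 1895), but these ignore the pairs. The splits that part all 5 pairs number 16, too few for a share under 0.05 (highest other 1398), and those that part 3 pairs gave up to 2249. The pretreated arrays had 10 splits, too few for a share under 0.05 (real 2300, highest other 2; 1 as large).

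Where the real count was 0 in limma's test, every split gave as many. These were, with 100 splits, the compounds compared in the pretreated PFC (highest other 1) and striatum (3), the doses in the naive striatum (355), the regions' stimulant effects in the naive (139) and pretreated cohort (285), and the genes shared by all 3 stimulants in the naive PFC (0), naive striatum (0) and pretreated striatum (0).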
